A study of Gallus gallus with 8 samples.

How the data were processed

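Gene expression was measured in retinas of chick embryos with a 1-colour oligonucleotide array, the Affymetrix Chicken Genome Array. Per the labels, retinas were electroporated at embryonic day 1.5 with RCAS, a replication-competent avian retroviral vector, and were recovered at embryonic day 6.5. The vector carried Wnt2b, Delta-1 or c-hairy1, or had no insert (control). Each of the 4 groups had 2 arrays, 8 in all. Groups and replicate numbers were taken from the sample titles. The description of control replicate 2 also names c-hairy1 in one sentence, against its title and the rest of its labels. It was kept as a control, and its signal for the c-hairy1 gene is given with the results. The labels do not say whether the 2 replicates of a group came from separate embryos, so the p-values measure the spread between these samples, which may be partly technical.

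The deposited values were signal intensity per probe set on a linear scale, made with GCOS 1.4 per the submitters' processing notes. Per the labels' protocols, RNA was extracted with Trizol and purified on an oligo-dT column before labelling. The design text also mentions a second program with similar results, whose values were not used here. The settings and the target value of any scaling were not given in the sources used here. The table held 38535 probe sets, of which 37693 were of chicken, 96 were array controls and 746 were of viruses or other records of no chicken transcript. The values ran from 0.0699 to 19161 with 0 missing.

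The depth of an array experiment lies in its number of arrays, and that number limits the precision here: the fit had 4 residual degrees of freedom plus 8.24 from the prior, and the median standard error of a log2 fold change was 0.246. The array medians ran from 33.28 to 38.75, and the ratios of 3' to 5' probe sets from 1.39 to 1.70 for actin and from 0.962 to 1.04 for GAPDH. Pearson's r across probe sets between the 2 arrays of a group was 0.961 to 0.972. Each c-hairy1 array had a higher r with an array of another group (0.967 and 0.966) than with its own replicate (0.961).

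The design, the gene lists, the rule for the genes to name and most alternatives were fixed before the data were examined. The written rule was to keep the deposited scaling if the arrays had near-equal trimmed means and to apply quantile normalization otherwise. The rule had no numeric tolerance. The trimmed means (2% left out at each end) ran from 141.2 to 177.6 and were not taken as near-equal, so the main values were quantile normalized. Values as deposited became an alternative, chosen after seeing the data. On the deposited scale the median log2 fold change of all tested probe sets was 0.148 for Delta-1 against control, -0.118 for c-hairy1 against control, -0.145 for Wnt2b against Delta-1 and -0.257 for c-hairy1 against Delta-1. It was -0.02 for Wnt2b against control and 0.094 for Wnt2b against c-hairy1.

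A pseudocount of 10.45, the 25th percentile of all values, was added before the log2 transform. Fold changes are on the log2(value + pseudocount) scale, which understates the change of dim genes. Probe sets under the 40th percentile of mean log2 value were left out, and 22616 were tested. The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) over all 8 arrays, with Benjamini-Hochberg adjustment and a threshold of 0.05. Values are given as log2 fold change ± standard error with 2 arrays per group. The 3 treatments were compared with control and with each other, which made 6 comparisons. Of these, 4 were main comparisons, the 3 against control and Wnt2b against Delta-1. A second rule of size counted probe sets changed at least 2-fold in all 4 array pairs of a comparison, beside the same count for the 2 other ways to part the 4 arrays.

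Probe sets were named from the platform's annotation. Of those tested, 17855 had 1 gene symbol, 96 had several and 4665 had none. The single symbols stood for 10094 genes, and 17677 of these probe sets had a symbol in the RefSeq gene table of the assembly bGalGal1.mat.broiler.GRCg7b. That table gave only the chromosome, since the array's own build was not given in the sources used here. It placed 776 tested probe sets on chromosome Z and 24 on W.

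The genes named in a main comparison were the delivered genes and, in each direction, up to 12 with the largest fold change among probe sets with 1 symbol that passed the threshold and whose arrays did not overlap between the groups. LOC numbers and predicted open reading frames were set aside unless under 12 others existed. Where fewer than 12 passed, up to 8 were filled in by the smallest unadjusted p among those changed 2-fold, as values that did not pass. From each list described, the 4 members with the smallest p were named, whether they passed or not. Any other gene is named as chosen after its values were seen.

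The 26 gene lists covered Wnt feedback and target genes, Wnt receptors and antagonists, the Notch pathway, and response genes of BMP and TGF-beta, FGF, Hedgehog and retinoic acid. Others held proneural factors, progenitors, cell cycle, ganglion cells and general neurons, photoreceptors, horizontal and amacrine cells, bipolar cells, Mueller glia, the ciliary margin, and retinal patterning. Tissues or cells that a dissected retina could carry along had lists too: pigment epithelium, lens, erythroid cells, mesenchyme with vessels and muscle, and macrophages with microglia. The last 4 were interferon response, cell adhesion, hypoxia and glycolysis, and cell stress. Each gene entered with its brightest probe set. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. With the estimated correlation 0 of the 26 lists passed in each of the 6 comparisons, with 0.056 the lowest adjusted p. Every list call here thus rests on the test with the preset value. The estimate was above 0.01 for some called lists, such as neurons (0.29) and proneural factors (0.31). It was under 0.01 for others, such as FGF response (-0.012) and Mueller glia (-0.033). For those a larger correlation does not account for the lost call. The change in p with the estimate thus does not measure gene correlation alone.

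The scripts were tested on simulated data. For Wnt2b against control, with 200 of 22616 probe sets changed in each of 20 draws, 51.1% of those changed 2-fold and 95.2% of those changed 4-fold were recovered. False calls made up 6.2% of all calls, and an unchanged comparison had at most 1. For Delta-1 against control, the neuron list shifted by -0.5 was called in 20 of 20 draws, with 3 calls of other lists in all draws together. The simulated probe sets were drawn independently of each other, while the estimated correlation within the neuron list was 0.29. These simulated rates therefore do not give the error rates in correlated data. The treatments share the control arrays, so correlations between their effects are given beside values simulated for unchanged groups.

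The alternatives tried were another pseudocount or none, another filter or none, median centring, values as deposited, eBayes without the trend, a fit of only the 4 arrays compared, the replicate number as a term, and each array left out in turn. For the lists, the estimated correlation and the mean over a gene's probe sets were added. Leaving out probe sets of chromosomes Z and W, and the delivered genes from the lists, was chosen after seeing the data. With 2 arrays per group, other regroupings and a search for outlying arrays within groups were not run.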

Results

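The transcripts of whole chick retinas were measured at embryonic day 6.5, when neurons were still being born, on 8 arrays of 4 groups with 2 arrays each. The groups had received RCAS carrying Wnt2b, a secreted Wnt ligand, Delta-1, a ligand of the Notch receptor, or c-hairy1, a basic helix-loop-helix repressor of the Hes family, or the vector with no insert as control. The labels describe all 3 delivered genes as blocking the formation of neurons. The deposited signals are in the arrays' linear intensity units, and fold changes are limma estimates on the log2 scale with 2 arrays per group.

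Each delivered gene was far above the other groups in the arrays that carried its name. WNT2B, on chromosome 26, had signals of 10220 and 8706 with Wnt2b and 3.442 to 21.11 in the other 6 arrays (log2 fold change against control 9.36 ± 0.32, adjusted p = 2.69e-08). DLL1, the gene of Delta-1 on chromosome 3, had signals of 12880 and 12820 with Delta-1 and 383.4 to 608.2 elsewhere (4.27 ± 0.14, adjusted p = 1.25e-08). HES4, the gene of c-hairy1 on chromosome 21, had signals of 12100 and 12970 with c-hairy1 and 383.8 to 800.3 elsewhere (4.99 ± 0.21, adjusted p = 2.31e-07). Control replicate 2, whose description also names c-hairy1, had the lowest HES4 signal of all arrays, 383.8. The second probe set of each gene did not follow the delivered sequence. That of DLL1 fell with Delta-1, from 1428 and 1257 in control to 756.5 and 636.4 (-1.13 ± 0.15, adjusted p = 0.00347). That of HES4 had a log2 fold change of -0.25 with c-hairy1 (adjusted p = 0.863) and rose with Wnt2b (0.87 ± 0.20, adjusted p = 0.0465). That of WNT2B was too dim to be tested, at 0.527 to 13.1.

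**Figure D1:**
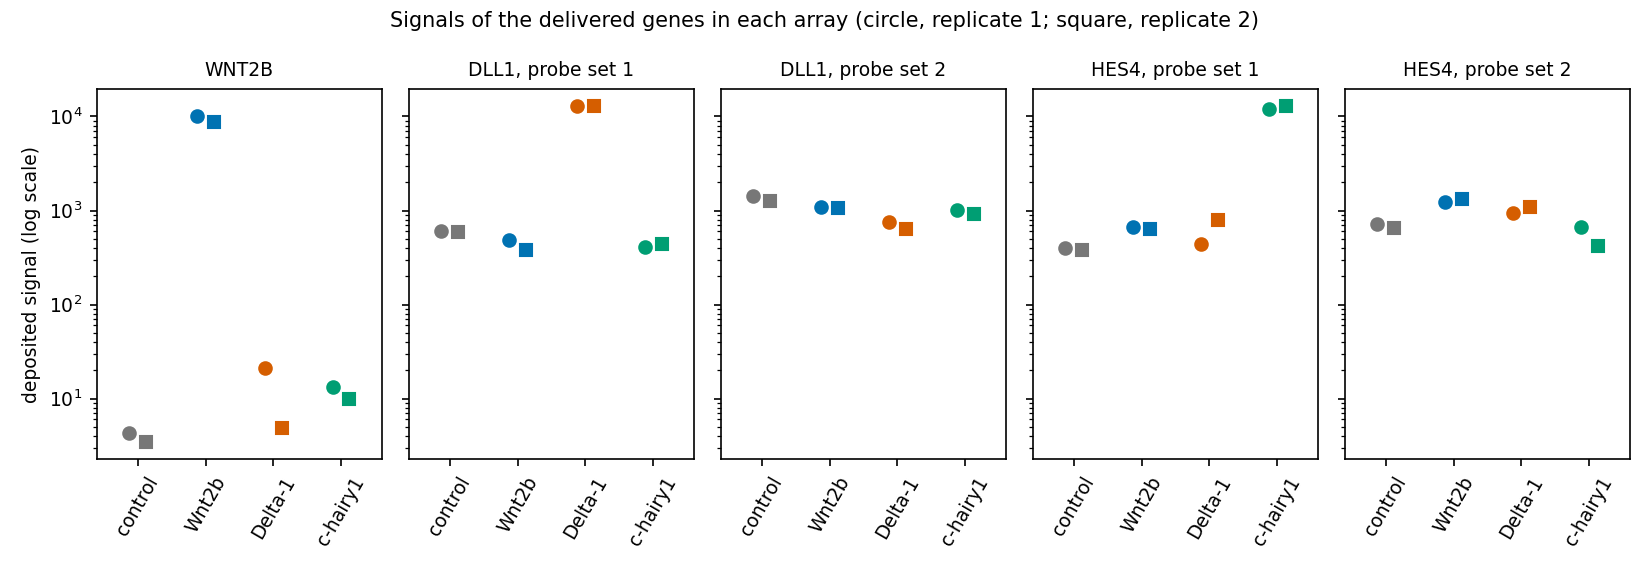
Signal per array (log axis, deposited intensity units) of 1 probe set of WNT2B, 2 of DLL1 and 2 of HES4 in the 4 groups, with circles for replicate 1 and squares for replicate 2. WNT2B reached 10220 and 8706 with Wnt2b, DLL1 12880 and 12820 with Delta-1, and HES4 12100 and 12970 with c-hairy1, each in its first probe set.

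Wnt2b against control asked which genes respond to the Wnt ligand in the retina. The lists of FGF response and ciliary margin genes rose, with single genes of Wnt feedback and retinoid metabolism, and the lists of neuronal genes fell, each call lost with an estimated correlation (adjusted p = 0.13 to 0.38). NOTUM, a secreted enzyme that inactivates Wnt proteins, rose by 3.38 ± 0.26 on the log2 scale (adjusted p = 7.84e-05), from a mean signal of 27.8 to 387. CACNG3, a gamma subunit of calcium channels, rose by 3.77 ± 0.19 (adjusted p = 9.62e-07), and FGF8, a fibroblast growth factor, by 2.63 ± 0.20 (adjusted p = 7.84e-05). RDH10, which oxidizes retinol, rose by 2.92 ± 0.23 (adjusted p = 8.72e-05), with all 3 of its probe sets called. SNAP25, a protein of synaptic vesicle fusion, fell by 2.02 ± 0.36 (adjusted p = 0.0157), with 3 of its 4 probe sets called.

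After WNT2B, the largest increases among named genes were those of the syntaxin STX19 (3.79 ± 0.38), CACNG3, FAM84A (3.48 ± 0.32), NOTUM and NPR3, the clearance receptor of natriuretic peptides on chromosome Z (3.30 ± 0.49). They were followed by MGLL, which breaks down monoacylglycerols (3.07 ± 0.56), RASL11AL (2.98 ± 0.32), RDH10, CLYBL (2.78 ± 0.60), FGF8 and LECT1, the cartilage protein chondromodulin (2.58 ± 0.55). The largest decreases were those of MLIP (-3.02 ± 0.37), netrin-G2 or NTNG2 (-2.88 ± 0.36), FXYD6 (-2.53 ± 0.48), FGF1 (-2.48 ± 0.41), ANKFN1 (-2.39 ± 0.42) and TBX5, a transcription factor of the dorsal retina (-2.25 ± 0.41). SPOCK1 (-2.13 ± 0.48, passing in 7 of 12 other settings), B3GAT2 (-2.13 ± 0.41), the inhibin subunit INHBB (-2.13 ± 0.45), the photoreceptor nuclear receptor NR2E3 (-2.04 ± 0.42), SNAP25 and NRIP2 (-1.97 ± 0.43) came next. MLIP, NTNG2 and INHBB each had another probe set of opposite sign.

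Of 17 tested Wnt feedback and target genes, 4 rose, 1 fell and 12 did not pass (6 and 1 when adjusted over the list alone). NKD1, an antagonist that binds Dishevelled, rose by 2.08 ± 0.27 (adjusted p = 0.00299) and LEF1, a DNA-binding partner of beta-catenin, by 1.62 ± 0.29 (adjusted p = 0.0156), beside NOTUM and MYC (0.99 ± 0.23). SP8, a zinc-finger factor, fell by 1.12 ± 0.18 (adjusted p = 0.011). The list as a whole did not pass, with a median of 0.15 (camera adjusted p = 0.0556, and adjusted p = 0.32 with an estimated correlation). It passed in 9 other settings: with median centring (adjusted p = 0.03), on the deposited scale (0.0362), with the mean over probe sets (0.0271) or the pseudocount at the 50th percentile (0.0417), without control replicate 1 (0.0217), without Wnt2b replicate 2 (0.0156), without either Delta-1 array (0.0396 and 0.0258) and with the delivered genes left out (0.0489). Of 18 genes in the list of Wnt receptors and antagonists, 2 fell, DKK3 (-0.68 ± 0.14, passing in 11 of 18 other settings) and SFRP1 (-0.64 ± 0.15, in 7 of 18). The other 16 did not pass (2 higher and 2 lower when adjusted over the list alone). This list had a median of -0.02 and a mean of 0.07 (camera adjusted p = 0.791).

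The FGF response list was higher with Wnt2b: 5 of its 16 genes rose and 11 did not pass, and 12 rose and 1 fell when adjusted over the list alone. Besides FGF8 these were SPRY2, a feedback inhibitor of receptor tyrosine kinases (1.46 ± 0.16), the receptor FGFR2 (1.60 ± 0.24), the ETS factor ETV4 (0.95 ± 0.20) and the ERK phosphatase DUSP6 (1.03 ± 0.24). The list's median was 0.71 (camera adjusted p = 3.09e-06, and adjusted p = 0.13 with an estimated correlation). Of 21 genes of the ciliary margin, the rim of the retina, 6 rose and 15 did not pass (8 higher and 1 lower over the list alone). Collagen IX chain COL9A1 rose by 2.52 ± 0.33, cyclin D2 or CCND2 by 1.13 ± 0.17 and WFDC1 by 1.08 ± 0.14, beside RDH10. The median was 0.64 (camera adjusted p = 0.00145, and adjusted p = 0.27 with an estimated correlation). Without Wnt2b replicate 1 the ciliary margin list did not pass (0.49, adjusted p = 0.0587).

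Of 32 genes of ganglion cells and general neurons, 9 fell with Wnt2b and 23 did not pass (17 fell when adjusted over the list alone). SNAP25 (-1.88 ± 0.28 in its brightest probe set), the stathmin STMN3 (-1.45 ± 0.24), the acetylcholine receptor subunit CHRNB3 (-1.79 ± 0.32) and DPYSL3 (-0.98 ± 0.18) were among them. The median was -0.79 (camera adjusted p = 8.14e-10, and adjusted p = 0.32 with an estimated correlation). Of 17 proneural and early neurogenic factors 4 fell and 13 did not pass (2 higher and 10 lower over the list alone): HES6 (-1.53 ± 0.20), BTG2 (-1.28 ± 0.21), NHLH2 (-1.09 ± 0.17) and SOX4 (-0.88 ± 0.18). Their median was -0.69 (camera adjusted p = 0.000164, and adjusted p = 0.38 with an estimated correlation). Of 13 genes of horizontal and amacrine cells 5 fell (1 higher and 7 lower over the list alone), the AP-2 factor TFAP2B (-1.96 ± 0.34), SLC32A1 (-1.70 ± 0.40), PROX1 (-1.47 ± 0.31), DLX5 (-1.41 ± 0.30) and calretinin or CALB2 (-1.31 ± 0.20). Of 15 photoreceptor genes 3 fell (7 over the list alone), NR2E3, OTX2 (-1.32 ± 0.29) and RXRG (-1.26 ± 0.25), and NEUROD1 had -1.08 (adjusted p = 0.0535). The medians of these lists were -0.79 (camera adjusted p = 0.000606) and -0.59 (0.00198), and with an estimated correlation adjusted p = 0.32 and 0.38.

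Of 16 genes of the Notch pathway, 4 fell with Wnt2b and 12 did not pass (3 higher and 7 lower over the list alone). They were HES6, the Notch targets HEY1 (-1.11 ± 0.20) and HES5 (-0.94 ± 0.19), and LFNG, a glycosyltransferase acting on Notch (-0.66 ± 0.15, passing in 9 of 18 other settings). The list did not pass (median -0.37, camera adjusted p = 0.0672, and adjusted p = 0.38 with an estimated correlation), but passed in 5 other settings: without Wnt2b replicate 1 (-0.51, adjusted p = 0.0167), with the filter at the 60th percentile (-0.53, 0.00407), with the mean over probe sets (-0.40, 0.0256), with the replicate block (-0.37, 0.0453) and without its delivered members DLL1 and HES4 (-0.406, 0.0482). Of 10 genes of Mueller glia, 3 fell and 7 did not pass (1 higher and 5 lower over the list alone): FXYD6, CRYM (-0.85 ± 0.19) and DKK3. CA2 had 0.32 (adjusted p = 0.0585). Their median was -0.47 (camera adjusted p = 0.0194, and adjusted p = 0.32 with an estimated correlation), and without control replicate 1 the list did not pass (-0.44, adjusted p = 0.175).

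The other lists did not pass against control. Their medians with Wnt2b were -0.06 for 22 progenitor genes (camera adjusted p = 0.733), 0.01 for 35 cell cycle genes (mean -0.01, adjusted p = 0.86), -0.09 for 7 genes of bipolar cells (0.733), -0.47 for 6 of the pigment epithelium (0.129) and 0.41 for 8 of the lens (0.647). They were -0.27 for 7 erythroid genes (0.647), 0.27 for 14 of mesenchyme, vessels and muscle (0.266), 0.25 for 7 of macrophages and microglia (0.155) and 0.01 for 9 of the interferon response (mean -0.05, adjusted p = 0.698). The BMP and TGF-beta list had 0.01 (0.811), the Hedgehog list 0.32 (0.482), the retinoic acid list 0.03 (0.413), the patterning list 0.12 (0.129), the adhesion list 0.18 (0.129), the hypoxia list 0.16 (0.155) and the stress list 0.08 (0.482). The Hedgehog, patterning, adhesion, erythroid and macrophage lists passed in 1 other setting each, the last with a reversed median (-0.214 without Wnt2b replicate 2). Besides genes named above or of the retinoic acid list, single members passed in some of them: FOXD1, a factor of the temporal retina on chromosome Z (1.39 ± 0.18), TGFBI (1.20 ± 0.23), CA9 (0.82 ± 0.13), TRPM1 (0.74 ± 0.16), PAX6 (-0.61 ± 0.13), the crystallin CRYBA4 (-0.93 ± 0.16) and E2F1 (-1.14 ± 0.22). FOXD1, TGFBI, CA9, TRPM1, PAX6, CRYBA4 and E2F1, like MYC, DUSP6 and SLC32A1, were chosen after their values were seen.

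In all, 515 of 22616 probe sets passed with Wnt2b, 249 higher and 266 lower (48.3% higher), which held 160 named genes that rose and 186 that fell. At an unadjusted p under 0.05 there were 3411, where chance gives 1131. By size, 285 changed at least 2-fold in all array pairs (158 higher and 127 lower), against 34 and 41 for the 2 other ways to part the 4 arrays. The 24 tested W-linked probe sets had a median of -0.13. The number called fell to 62 (50 higher and 12 lower) without control replicate 1, to 123 (96 and 27) without control replicate 2, to 69 (48 and 21) without Wnt2b replicate 2, to 28 (23 and 5) without the intensity trend and to 238 (135 and 103) without the filter. Of 57 called values followed through the settings, which are not all of those named here, 9 passed in every setting in which they were tested, those of WNT2B, CACNG3, FAM84A, FGF8, NOTUM, SPRY2, STX19 and 2 probe sets of RDH10, while 38, 33, 38 and 9 were lost without control replicate 1, control replicate 2, Wnt2b replicate 2 and Wnt2b replicate 1.

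Delta-1 against control asked what the Notch ligand changes. The lists of ganglion cells and general neurons, of proneural factors and of horizontal and amacrine cells fell (adjusted p = 0.26 each with an estimated correlation), as did that of photoreceptors (adjusted p = 0.35). NEFM, the medium neurofilament chain, fell by 1.79 ± 0.14 on the log2 scale (adjusted p = 9.87e-05), and STMN2, a microtubule-binding stathmin, by 2.02 ± 0.22 (adjusted p = 0.00115). ATOH7, the basic helix-loop-helix factor needed for ganglion cells, fell by 1.53 ± 0.18 (adjusted p = 0.00135) and NEUROD1, another factor of that family, by 1.94 ± 0.26 (adjusted p = 0.00339). CALB2 fell by 1.86 ± 0.20 (adjusted p = 0.00115). Of 24 tested W-linked probe sets 12 fell, with a median over all 24 of -1.74.

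Of the 32 genes of ganglion cells and general neurons, 17 fell with Delta-1 and 15 did not pass (24 fell when adjusted over the list alone). NEFL, the light neurofilament chain (-1.59 ± 0.19), STMN3 (-1.92 ± 0.24) and STMN2 (-1.44 ± 0.19 in its brightest probe set) stood beside NEFM. The median was -1.35 (camera adjusted p = 3.94e-22, and adjusted p = 0.26 with an estimated correlation). Of 17 proneural and early neurogenic factors, 10 fell and 7 did not pass (13 fell over the list alone), with ATOH7, NEUROD1, BTG2 (-1.42 ± 0.21) and NEUROG2 (-1.75 ± 0.29) first. Their median was -1.22 (camera adjusted p = 7.44e-13, and adjusted p = 0.26 with an estimated correlation). Beside these lists, the median of W-linked probe sets was -1.74 and that of 776 Z-linked ones 0.24, against 0.02 on other chromosomes.

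Of 15 photoreceptor genes 5 fell with Delta-1 and 10 did not pass (8 over the list alone): NEUROD1, RXRG (-1.86 ± 0.25), OTX2 (-1.74 ± 0.29), IMPG2 (-1.24 ± 0.23) and NR2E3 (-1.89 ± 0.42), the last chosen after its value was seen. The median was -1.03 (camera adjusted p = 4.13e-05, and adjusted p = 0.35 with an estimated correlation). Of 13 genes of horizontal and amacrine cells 3 fell and 10 did not pass (1 higher and 7 lower over the list alone): CALB2, TFAP2B (-1.80 ± 0.34) and the tachykinin gene TAC1 (-1.30 ± 0.25). TFAP2A had -1.11 (adjusted p = 0.0589). The median was -0.86 (camera adjusted p = 1.03e-05, and adjusted p = 0.26 with an estimated correlation). The Z-linked median of 0.24 and the W-linked median of -1.74 stood beside these lists too. The calls of these 4 neuronal lists were kept in each setting tried except the estimated correlation.

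Genes of the Notch pathway did not pass as a list with Delta-1 (median 0.06, camera adjusted p = 0.518), nor without the delivered DLL1 and HES4 (0.009, 0.995). Of 16, DLL1 itself rose and 15 did not pass (2 higher and 1 lower over the list alone). DLL4 had -1.02 (adjusted p = 0.065), HES5 0.58 (0.187) and HES6 -0.41 (0.465). Of the Wnt receptors and antagonists, SFRP1 (0.83 ± 0.15) and the receptor FZD5 (0.56 ± 0.12) rose and 16 did not pass (5 higher over the list alone), and FZD4 had 1.00 (0.082) and SFRP2 0.65 (0.134). That list's median was 0.17 (camera adjusted p = 0.14, and adjusted p = 0.70 with an estimated correlation), and it passed without control replicate 1 (0.22, adjusted p = 0.0472), without Delta-1 replicate 1 (0.30, adjusted p = 0.0355) and with the filter at the 60th percentile (0.36, adjusted p = 0.0217). Of the Wnt feedback genes, SP8 fell by 1.68 ± 0.18 and 16 did not pass (1 higher and 2 lower over the list alone). Their median was -0.03 (adjusted p = 0.589), or 0.08 with median centring and on the deposited scale. The 35 cell cycle genes had a median of 0.08 (adjusted p = 0.378) with 0 passed in limma and 4 at an unadjusted p under 0.05, and passed as a list on the deposited scale (0.235, adjusted p = 0.0307). The 10 Mueller glia genes had 0.06 (mean -0.04, adjusted p = 0.82). Of the FGF list, FGF8 rose by 1.12 ± 0.20 while FGF19 (-1.69 ± 0.13) and FGF3 (-1.50 ± 0.22) fell, with a median of 0.21 and a mean of -0.01 (adjusted p = 0.798). Those 3 genes were chosen after their values were seen. The pigment epithelium list did not pass (-0.17, camera adjusted p = 0.378), but passed with the mean over probe sets (-0.702, adjusted p = 0.0333). The W-linked median of -1.74 and the Z-linked median of 0.24 apply to these lists as well.

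With LOC numbers set aside, the largest increases with Delta-1 after DLL1 were those of MICALL2 (2.89 ± 0.39), the sarcomere protein MYOM3 (2.69 ± 0.48), the collagen receptor kinase DDR2 (2.03 ± 0.39), the matricellular protein CCN2 (1.82 ± 0.28) and KK34 (1.69 ± 0.20). APEH (1.59 ± 0.29, with another probe set of opposite sign), MSRB3 (1.56 ± 0.29), VWC2 (1.43 ± 0.27), GAMT (1.39 ± 0.28), the small heat shock protein CRYAB (1.37 ± 0.21) and CFC1 on chromosome Z (1.29 ± 0.27) followed. The largest decreases, likewise, were of 4 W-linked genes, HINTW (-7.41 ± 0.34), HNRNPKL (-4.50 ± 0.52), SPIN1L (-2.90 ± 0.32) and UBE2R2L (-2.80 ± 0.28). HINTW had signals of 20.5 and 90.4 with Delta-1 and of 7430 to 10300 in the other 6 arrays. They were followed by PLA2G5 (-2.59 ± 0.34), PFKFB3 (-2.28 ± 0.26, with 2 of its 4 probe sets of opposite sign), SNAP25 (-2.15 ± 0.36), chromogranin A or CHGA (-2.08 ± 0.30), STMN3 (-2.03 ± 0.28), STMN2, KLHL35 (-2.01 ± 0.33) and CBLN2 (-1.99 ± 0.33).

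**Figure D2:**
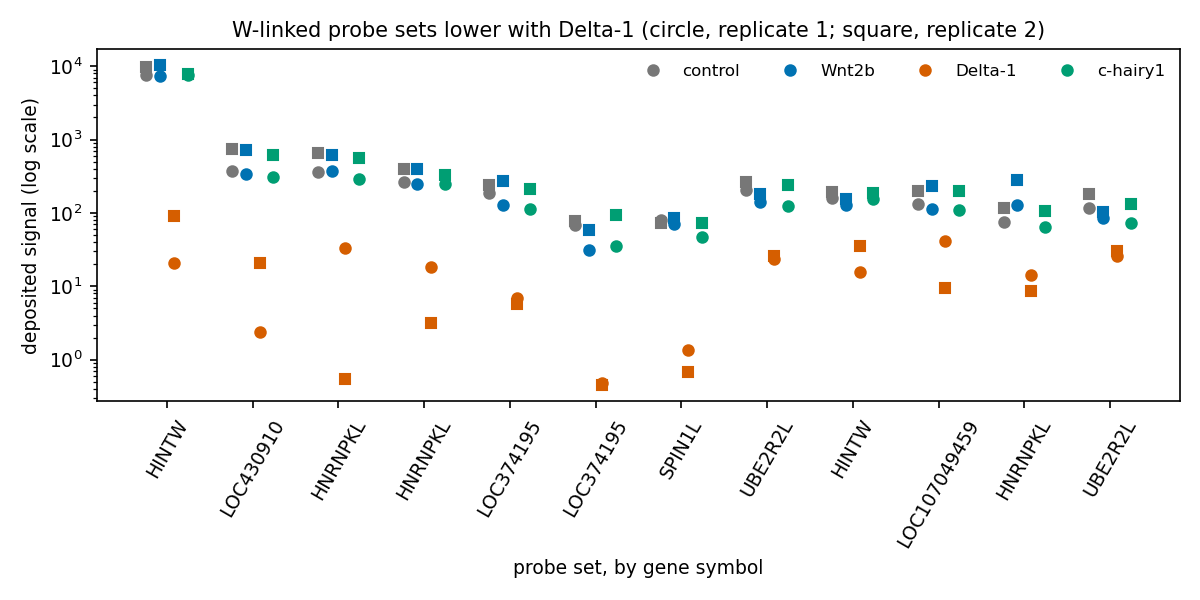
Signal per array (log axis, deposited intensity units) of the 12 W-linked probe sets that passed as lower with Delta-1, in the 4 groups. HINTW lay at 20.5 and 90.4 in the 2 Delta-1 arrays and at 7430 to 10300 in the other 6.

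In all, 383 probe sets passed with Delta-1, 76 higher and 307 lower, which held 50 named genes that rose and 199 that fell. The share of higher calls was 19.8% after quantile normalization, 40.5% with median centring and 46.3% on the deposited scale (213 higher and 247 lower). At an unadjusted p under 0.05 there were 2703. By size, 258 changed at least 2-fold in all array pairs (45 higher and 213 lower), against 41 and 30 for the other ways to part the arrays. Of the calls, 348 lay outside chromosomes Z and W or had no place. The count fell to 53 (8 higher and 45 lower) without control replicate 1 and likewise without Delta-1 replicate 2, to 169 (34 and 135) without control replicate 2, to 19 (4 and 15) without the intensity trend and to 227 (38 and 189) without the filter, and was 590 (142 and 448) with only the 4 arrays compared. Of 44 called values followed through the settings, which are not all of those named here, those of DLL1, CALB2, HINTW, NEFM, SPIN1L and UBE2R2L passed in every setting in which they were tested, while 26, 13, 27 and 6 were lost without control replicate 1, control replicate 2, Delta-1 replicate 2 and Delta-1 replicate 1.

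c-hairy1 against control asked the same of the Hes-family repressor. Besides HES4 itself, 1 gene passed, LOC107052719 (2.90 ± 0.34, adjusted p = 0.0208). As lists, neuronal, proneural, horizontal and amacrine genes were lower and ciliary margin and FGF genes higher, each with adjusted p = 0.35 with an estimated correlation. The list of ganglion cells and neurons had a median of -0.55 (camera adjusted p = 1.02e-09), with 0 members passing in limma over all genes, 17 at an unadjusted p under 0.05 and 10 lower when adjusted over the list alone. SNCG (-1.16 ± 0.24), CNTN2 (-1.15), STMN3 (-0.85) and DPYSL3 (-0.64) had the smallest p among them. The proneural list had a median of -0.66 (camera adjusted p = 7.36e-05), with 1 higher and 6 lower over the list alone, and its first members were NHLH1 (-0.94), HES6 (-0.74), SOX4 (-0.66) and DCX (0.62). Horizontal and amacrine genes had a median of -0.24 (camera adjusted p = 0.0111), with CALB2 at -1.31 ± 0.20, TFAP2B at -1.45, DLX5 at -1.14 and MEIS2 at 0.63 (1 higher and 4 lower over the list alone). That last list did not pass without c-hairy1 replicate 1 (-0.23, adjusted p = 0.119).

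The ciliary margin list had a median of 0.18 with c-hairy1 (camera adjusted p = 0.0154), with 0 members passing in limma over all genes, 7 at an unadjusted p under 0.05 and 7 higher over the list alone. COL9A1 had 2.09 ± 0.33, COL9A3 1.91 ± 0.32, RDH10 1.47 ± 0.25 and the zinc-finger factor ZIC1 1.15 ± 0.20, each with adjusted p = 0.126. The FGF list had a median of 0.19 (camera adjusted p = 0.0253), with 2 higher over the list alone, FGF8 at 0.86, SPRY2 at 0.69, SPRY1 at 0.68 and FGFR1 at 0.43. The ciliary margin list did not pass without c-hairy1 replicate 2 (0.21, adjusted p = 0.102), without control replicate 2 (0.22, 0.0706) or with the mean over probe sets (0.13, 0.0603), and the FGF list did not pass without c-hairy1 replicate 1 (0.19, 0.0993), without control replicate 2 (0.10, 0.236) or without the filter (0.13, 0.118).

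The Notch list did not pass with c-hairy1 (median -0.24, mean 0.01, camera adjusted p = 0.0566, and adjusted p = 0.35 with an estimated correlation). Of its 16 genes HES4 rose and 15 did not pass (1 higher and 4 lower over the list alone), with HEY1 at -1.14 ± 0.20 (adjusted p = 0.126), DTX4 at -1.14 (0.145) and HES6 at -0.74 (0.373). The list passed in 9 other settings: without the delivered DLL1 and HES4 (-0.243, adjusted p = 0.00577, and adjusted p = 0.31 with an estimated correlation), without c-hairy1 replicate 1 (-0.33, adjusted p = 0.00677), c-hairy1 replicate 2 (-0.23, 0.0273), Wnt2b replicate 1 (-0.24, 0.0278) or Wnt2b replicate 2 (-0.26, 0.0209), with the filter at the 60th percentile (-0.345, 0.00933), the mean over probe sets (-0.26, 0.0241), the pseudocount at the 50th percentile (-0.22, 0.0486) and the replicate block (-0.24, 0.0289). Of the lists not called with c-hairy1, interferon response also passed in 6 settings, retinoic acid in 5, hypoxia in 4, photoreceptors in 3, Mueller glia and adhesion in 2 each, and the mesenchyme and erythroid lists in 1 each. Other genes changed 2-fold that did not pass were NPY (2.04 ± 0.30, adjusted p = 0.105), OLFML3 (1.96 ± 0.34, 0.126), RDH10 in another probe set (1.58 ± 0.23, 0.105) and the endothelin receptor EDNRB (1.34 ± 0.23, 0.126). On the lower side were TBX5 (-2.10 ± 0.41, 0.169), YARS (-1.98, 0.235, with 2 of 3 probe sets of opposite sign), RPL12 (-1.52, 0.218, with another of opposite sign) and CSDC2 (-1.06, 0.259).

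In all, 2 probe sets passed with c-hairy1, and 1658 had an unadjusted p under 0.05 in limma, where chance gives 1131. By size, 82 changed at least 2-fold in all array pairs (53 higher and 29 lower), against 49 and 52 for the other ways to part the arrays. LOC107052719 did not pass without c-hairy1 replicate 2 (adjusted p = 0.125), without control replicate 1 (0.446), without the filter (0.14) or without the intensity trend (0.376), so the count was 1 there. The count was 6 without c-hairy1 replicate 1 and 5 without Wnt2b replicate 1 or without either Delta-1 array, 21 (17 higher and 4 lower) with only the 4 arrays compared and 13 (12 and 1) with the replicate block.

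**Figure D3:**
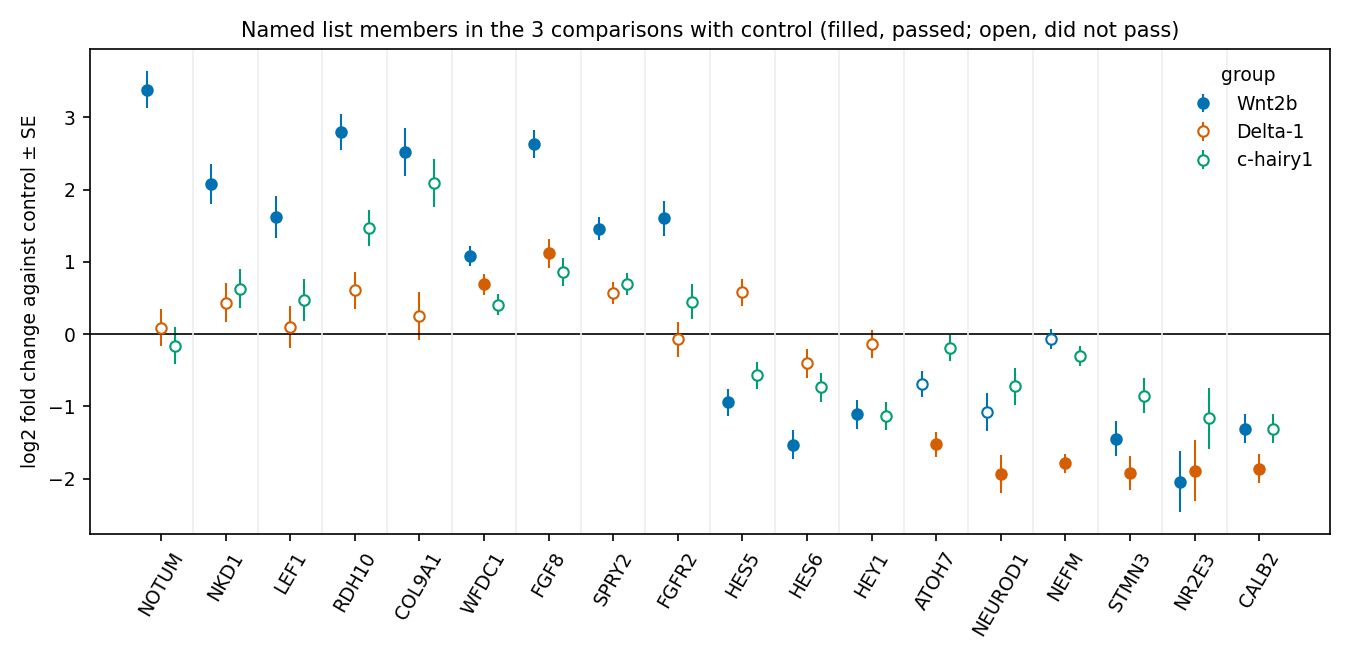
Log2 fold change against control with its standard error (bars, 2 arrays per group) of 18 genes with Wnt2b, Delta-1 and c-hairy1, filled where the gene passed at the threshold of 0.05. NOTUM stood at 3.38 with Wnt2b, NEFM at -1.79 with Delta-1 and COL9A1 at 2.09 with c-hairy1, the last unfilled.

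Wnt2b against Delta-1 asked which changes were particular to the Wnt ligand among treatments that hold back neurons, and the design text used it to pick candidate Wnt targets. NOTUM was higher with Wnt2b than with Delta-1 by 3.29 ± 0.26 (adjusted p = 7.12e-05), NKD1 by 1.64 ± 0.27 (adjusted p = 0.00975) and LEF1 by 1.52 ± 0.29 (adjusted p = 0.0207). TRABD2A, a membrane protease that inactivates Wnt proteins and lies on chromosome Z, was higher by 3.13 ± 0.39 (adjusted p = 0.00146). SFRP1, a secreted Wnt antagonist, was lower with Wnt2b (-1.47 ± 0.15, adjusted p = 0.000325), as were the Notch target HES5 (-1.52 ± 0.19, adjusted p = 0.0014) and DLL1 (-4.73 ± 0.14). W-linked probe sets had a median of 1.67 here, with 13 higher, and Z-linked ones -0.20.

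Of 17 Wnt feedback genes 3 were higher with Wnt2b than with Delta-1 and 14 did not pass (5 over the list alone), with SP8 at 0.56 (adjusted p = 0.22) and a median of 0.39 (camera adjusted p = 7.01e-05, and adjusted p = 0.11 with an estimated correlation). Of 16 FGF genes 6 were higher and 10 did not pass (8 over the list alone): FGF19 (1.43 ± 0.13), FGF8 (1.51 ± 0.20), FGFR2 (1.68 ± 0.24) and SPRY2 (0.89 ± 0.16) came first. Their median was 0.61 (camera adjusted p = 1.5e-09, and adjusted p = 0.056 with an estimated correlation). Of 21 ciliary margin genes 4 were higher and 17 did not pass (9 higher and 1 lower over the list alone), COL9A1 (2.27 ± 0.33), RDH10 (2.19 ± 0.25), CCND2 (1.09 ± 0.17) and ZIC1 (1.01 ± 0.20). The median was 0.08 (camera adjusted p = 0.0213, and adjusted p = 0.31 with an estimated correlation). That list did not pass without Wnt2b replicate 1 (0.19, adjusted p = 0.197) or without the Z- and W-linked probe sets (0.03, adjusted p = 0.0725). The W-linked median of 1.67 and the Z-linked median of -0.20 stood beside these lists.

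The lists of ganglion cells and neurons and of proneural factors were higher with Wnt2b than with Delta-1 (adjusted p = 0.54 each with an estimated correlation), while those of horizontal and amacrine cells (median 0.03, camera adjusted p = 0.466) and photoreceptors (0.33, 0.214, passing in 4 other settings) did not pass. Of 32 genes of ganglion cells and neurons, NEFM (1.72 ± 0.14, passing in all 18 other settings) and the adhesion protein NFASC (1.00 ± 0.22, in 6 of 18) were higher and 30 did not pass (5 over the list alone), with NEFL at 0.77 and UCHL1 at 0.53. Their median was 0.52 (camera adjusted p = 4.87e-05). Of 17 proneural factors NEUROG1 (2.04 ± 0.32) and ATOH7 (0.84 ± 0.18, passing in 7 of 18 other settings) were higher, HES6 was lower (-1.12 ± 0.20) and 14 did not pass (6 higher and 1 lower over the list alone), with BHLHE22 at 0.52 (adjusted p = 0.0771). Their median was 0.64 (camera adjusted p = 0.00172, and adjusted p = 0.54 with an estimated correlation). Neither list passed without Delta-1 replicate 2 (neurons 0.25, adjusted p = 0.111, and proneural 0.31, 0.261) or without Wnt2b replicate 1 (0.22, 0.146, and 0.42, 0.197). The W- and Z-linked medians beside them were 1.67 and -0.20.

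Of 16 Notch genes 5 were lower with Wnt2b than with Delta-1 and 11 did not pass (1 higher and 7 lower over the list alone), DLL1, HES5, HES6, LFNG (-0.94 ± 0.15) and HEY1 (-0.98 ± 0.20), the last chosen after its value was seen. The median was -0.09 (camera adjusted p = 0.0134, and adjusted p = 0.41 with an estimated correlation), with 8 values above and 8 below 0. This list holds the delivered DLL1 and HES4, and without them it did not pass (-0.094, adjusted p = 0.0719). It also did not pass without Delta-1 replicate 1 (-0.15, adjusted p = 0.267), without Delta-1 replicate 2 (-0.21, 0.354) or on the deposited scale (-0.27, 0.0631), and without the filter its median was 0.06 (0.208). Of 10 Mueller glia genes CRYM (-1.15 ± 0.19) and DKK3 (-0.68 ± 0.14) were lower and 8 did not pass (4 over the list alone), with CLU at -2.02 (adjusted p = 0.126) and GLUL at -0.93 (0.148). The median was -0.57 (camera adjusted p = 0.00172, and adjusted p = 0.17 with an estimated correlation). The 14 hypoxia and glycolysis genes had a median of 0.16 (camera adjusted p = 0.0391, and adjusted p = 0.50 with an estimated correlation). That call was lost in 10 settings besides the estimated correlation, among them without Delta-1 replicate 2 (0.13, 0.22), Wnt2b replicate 1 (0.12, 0.218), control replicate 1 (0.17, 0.056) and control replicate 2 (0.16, 0.0569), and 0 of its members passed in limma, with 4 at an unadjusted p under 0.05. The W- and Z-linked medians were 1.67 and -0.20 beside these lists too.

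Among named genes the largest values higher with Wnt2b, after WNT2B (8.75 ± 0.32), were those of the W-linked HINTW (7.38), HNRNPKL (4.50) and SPIN1L (2.96), and of STX19 (3.73), NOTUM, FAM84A (3.27), TSPO2 (3.20), TRABD2A, MGLL (2.98), NPR3 (2.90) and CLYBL (2.87). The lowest were DLL1, MLIP (-4.20), NTNG2 (-3.67), COL23A1 (-2.84, with another probe set of opposite sign), VWC2 (-2.51), FGF1 (-2.48), GPR146 (-2.44), LZTFL1 (-2.42), ANKFN1 (-2.27), MYOM3 (-2.26), TBX5 (-1.99) and CGNL1 (-1.92).

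In all, 314 probe sets passed between Wnt2b and Delta-1, 168 higher with Wnt2b and 146 lower. The share of higher calls was 53.5%, 33.5% with median centring and 27.8% on the deposited scale (141 higher and 367 lower). At an unadjusted p under 0.05 there were 2577, and 218 changed at least 2-fold in all array pairs (130 higher and 88 lower), against 34 and 27 for the other ways to part the arrays. The count was 120 (80 higher and 40 lower) without Delta-1 replicate 1, 209 (121 and 88) without Delta-1 replicate 2, 190 (84 and 106) without Wnt2b replicate 1, 124 (66 and 58) without Wnt2b replicate 2, 40 (28 and 12) without the intensity trend and 205 (115 and 90) without the filter. Of 47 called values followed through the settings, which are not all of those named here, 14 passed in every setting in which they were tested, and 20, 13, 14 and 21 were lost without those same arrays in turn.

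The selection in the design text took genes higher with Wnt2b than in control and Delta-1 retinas. When both tests had to pass, it held 80 probe sets with 54 named genes, counting the delivered WNT2B itself. At least 2-fold in all array pairs of both comparisons were 54 probe sets with 32 named genes, and 45 met both rules. NOTUM, CACNG3, FAM84A, STX19, NPR3, MGLL, RASL11AL, RDH10, FGF8 and COL9A1 were in the first group. Of the 80, 27 were also higher than with c-hairy1, the delivered WNT2B among them (8.73, adjusted p = 6.16e-08). So were NOTUM (3.54, adjusted p = 4.62e-05), CACNG3 (2.75, 2.56e-05) and FGF8 (1.77, 0.00323), while COL9A1 had 0.43 (0.737). The genes of this paragraph were named for other comparisons. The 80 became 34 without control replicate 1, 41 without control replicate 2, 34 without Delta-1 replicate 1, 42 without Wnt2b replicate 1, 18 without Wnt2b replicate 2, 8 without the intensity trend and 51 without the filter.

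The effects of the treatments were compared with each other, which share the control arrays. Wnt2b and Delta-1 had 22 probe sets higher in both (0.819 if the lists were independent) and 115 lower in both (3.6), and 5 passed in opposite directions. Of those 5, SFRP1 was lower with Wnt2b and higher with Delta-1 in both of its probe sets (-0.64 and 0.83, passing in 7 and 13 of 18 other settings, and -0.72 and 0.73), as was PLPP3 (-0.75 and 0.69), and 2 had no symbol. Among genes higher in both were FGF8 (2.63 with Wnt2b and 1.12 with Delta-1), CACNG3 (3.77 and 1.24), the growth regulator MYCN (1.04 and 0.81) and the polarity gene CRB2 (1.13 and 1.15), and OTX2 was among those lower in both (-1.31 and -1.74). The genes of this paragraph were chosen after their values were seen. Across 22611 probe sets, which are not independent replicates, the effects of Wnt2b and Delta-1 had r = 0.532, those of Wnt2b and c-hairy1 0.556 and those of Delta-1 and c-hairy1 0.545, against 0.502, 0.50 and 0.50 simulated for unchanged groups. The covariances were 0.104, 0.0938 and 0.0867, against 0.0464, 0.0462 and 0.0461 simulated, a difference of 0.0576, 0.0476 and 0.0406. The 2 control arrays were not split between the treatments, and the overlaps were set only against independent lists. Part of the excess in overlap may therefore come from the shared controls.

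The last comparisons set c-hairy1 beside the other treatments. Against Delta-1, the list of ganglion cells and neurons was higher with c-hairy1: of 32 genes NEFM (1.49 ± 0.14), NFASC (1.27 ± 0.22) and NEFL (1.03 ± 0.19) were higher and 29 did not pass (17 over the list alone), with a median of 0.70 (camera adjusted p = 2.52e-11). This list and the 5 others called in this comparison had adjusted p = 0.30 with an estimated correlation. The medians were 0.60 for proneural factors (camera adjusted p = 1.24e-07), 0.81 for photoreceptors (0.000278) and 0.42 for horizontal and amacrine cells (0.00217), and ATOH7 (1.33 ± 0.18) and IMPG2 (1.35 ± 0.23) passed in them. The Notch list was lower (median -0.31, camera adjusted p = 0.0152), with HES5 at -1.14 ± 0.19 beside the delivered DLL1 and HES4, without which the list still passed (-0.315, adjusted p = 0.0112, and adjusted p = 0.30 with an estimated correlation), and the hypoxia list higher (0.23, 0.0241). The Notch list did not pass without Delta-1 replicate 1 (-0.31, 0.604) or 2 (-0.15, 0.356), the horizontal and amacrine list without Delta-1 replicate 2 (0.16, 0.134), and the hypoxia list without c-hairy1 replicate 2 (0.19, 0.226) or without Delta-1 replicate 1 (0.17, 0.0601) or 2 (0.13, 0.11). Neither the Notch nor the hypoxia list passed on the deposited scale (-0.56, 0.157, and 0.06, 0.0968), with median centring (-0.50, 0.0801, and 0.12, 0.0801) or without the filter (-0.23, 0.129, and 0.13, 0.0951). Beside these lists, erythroid genes had a median of 0.58 (adjusted p = 0.153, passing in 6 other settings) and Mueller glia genes -0.26 (0.0524, passing in 6), and the cell cycle list (0.0655) passed in 3, among them the deposited scale (-0.395, 0.0016), as did the interferon list in 3 and the retinoic acid list in 2. W-linked probe sets had a median of 1.96 and Z-linked ones -0.21. Here 81 probe sets passed, 67 higher with c-hairy1 and 14 lower (82.7% higher, 53.7% with median centring and 30.9% on the deposited scale, 43 higher and 96 lower). The count was 23 without c-hairy1 replicate 2, 48 and 46 without control replicates 1 and 2, 50 and 24 without Delta-1 replicates 1 and 2, 10 (9 and 1) without the intensity trend, 32 (28 and 4) without the filter and 39 (30 and 9) with only the 4 arrays compared.

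Wnt2b against c-hairy1 gave 60 calls, 33 higher with Wnt2b and 27 lower (55% higher, 69.2% with median centring and 77% on the deposited scale, 57 higher and 17 lower). Higher were NOTUM and FGF8, and the lists of FGF response (median 0.45, camera adjusted p = 2.35e-05) and Wnt feedback (0.29, 0.0182), with adjusted p = 0.16 and 0.34 with an estimated correlation. SFRP1 was lower with Wnt2b (-1.12 ± 0.15, adjusted p = 0.0103), as were the lists of photoreceptors (-0.36, 0.0163) and interferon response (-0.34, 0.0163), in which 0 members passed in limma, with 4 and 1 at an unadjusted p under 0.05. With an estimated correlation these 2 lists had adjusted p = 0.58 and 0.34. The Wnt feedback list did not pass without c-hairy1 replicate 1 (0.15, 0.0753) or Wnt2b replicate 1 (0.25, 0.0805) or with the filter at the 60th percentile (0.05, 0.217), the photoreceptor list without c-hairy1 replicate 2 (-0.37, 0.20) or Wnt2b replicate 2 (-0.28, 0.195), and the interferon list without c-hairy1 replicate 2 (-0.30, 0.0777) or Wnt2b replicate 1 (-0.29, 0.139) or with that filter (-0.31, 0.167). The list of ganglion cells and neurons did not pass here (median -0.25, camera adjusted p = 0.0739, and adjusted p = 0.73 with an estimated correlation), but passed in 10 other settings, among them median centring (-0.19, 0.0181) and without Wnt2b replicate 1 (-0.405, 0.000333). Also not called were the Hedgehog list (0.44, 0.0883, passing in 7 other settings), erythroid cells (-0.48, 0.105, in 5), patterning (0.31, 0.0811, in 4), ciliary margin (0.0867, in 3) and horizontal and amacrine cells (0.105, in 3). The count was 33 and 20 without c-hairy1 replicates 1 and 2, 33 and 29 without control replicates 1 and 2, 36 and 11 without Wnt2b replicates 1 and 2, 5 (3 and 2) without the intensity trend, 19 (10 and 9) without the filter, 39 (26 and 13) with only the 4 arrays compared and 22 (9 and 13) without a pseudocount. Members of lists in these last comparisons were chosen after their values were seen.

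**Figure D4:**
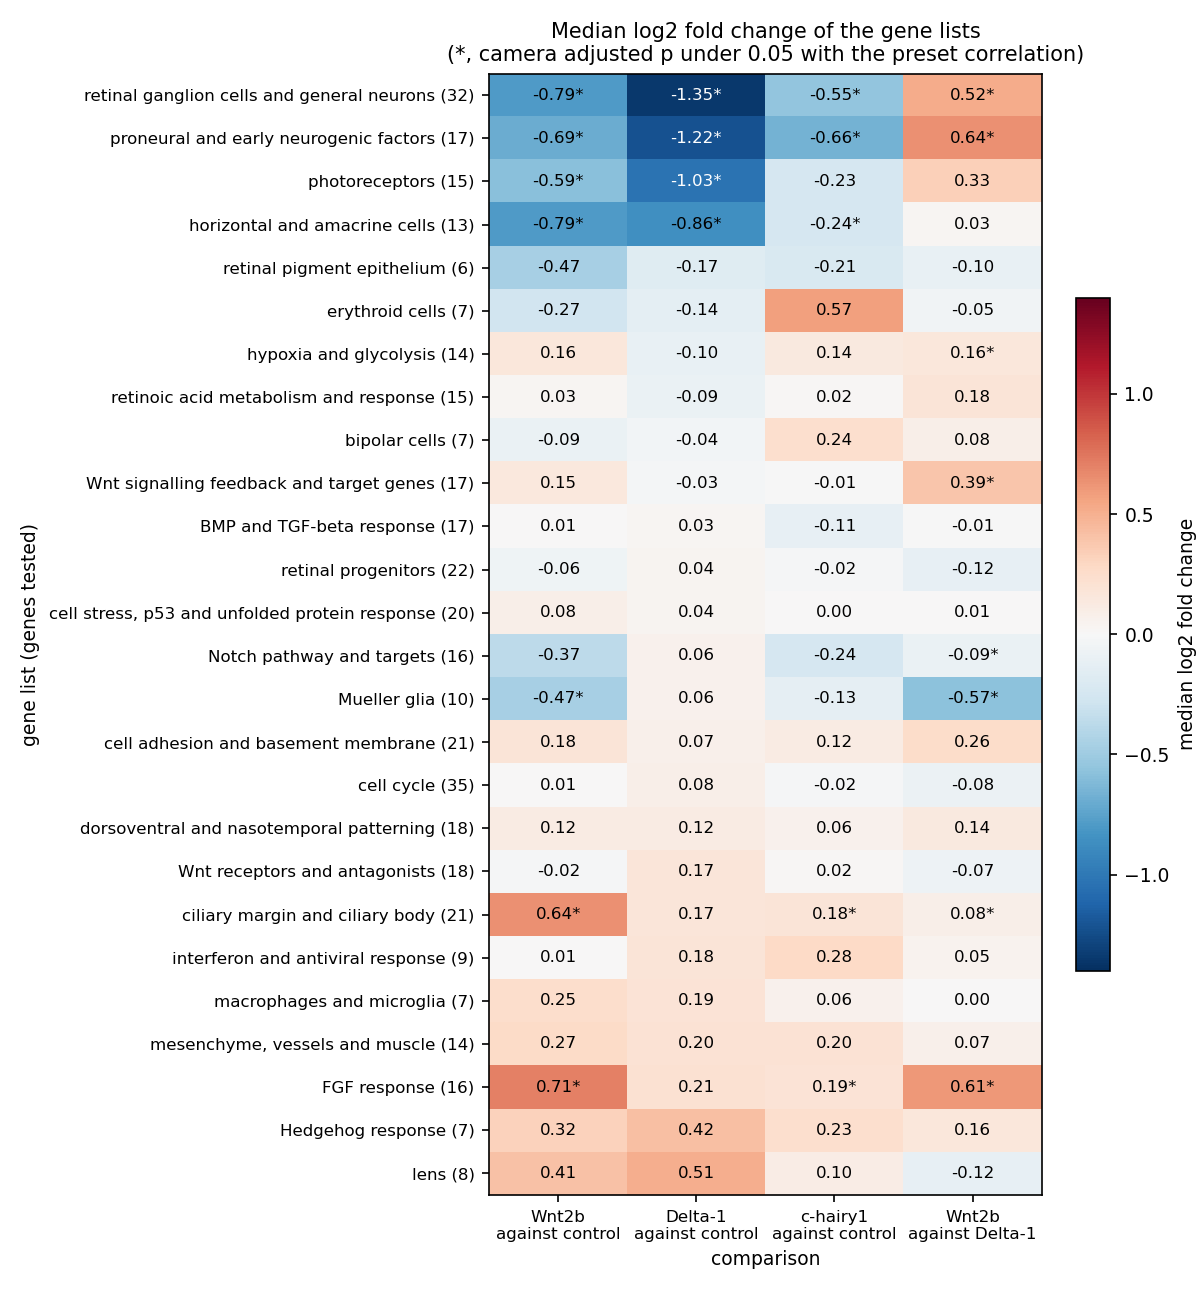
Median log2 fold change of the tested members of 26 gene lists (rows of the heat map) in 4 comparisons (columns), with a star where the list passed in camera at the preset correlation of 0.01. The list of ganglion cells and neurons stood at -0.79 with Wnt2b, -1.35 with Delta-1 and -0.55 with c-hairy1 against control, and at 0.52 in Wnt2b against Delta-1.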

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

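Both tests in this part were chosen only after the result was seen, and so was the rule that picked the probe set. Of the 746 probe sets of viruses or other records of no chicken transcript, which entered no comparison, 1 lay at least 2-fold above both control arrays in both arrays of a group with a mean signal of 100 or more. It is the probe set for the second coding region of its record. Its mean signal was 418 with Wnt2b (464 and 372), 353 with Delta-1 (333 and 373) and 1750 with c-hairy1 (1180 and 2330), against 31.3 in control (52.8 and 9.71). The probe set for the first coding region of the same record had 474 and 442 in control and 301 to 1190 in the other arrays.

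If both probe sets report the vector, a larger amount of vector RNA in the groups with an insert would raise both alike. The log2 ratio of the second to the first was at least 1.6 higher in every array with an insert than in either control. Whether the first probe set reports the vector was not examined, so this ratio cannot decide on the amount of vector RNA. Hybridization of the coding sequence of a single insert to the probes is argued against, since all 3 groups with an insert lay above control in both arrays. Sequence that the vectors with an insert share and the empty vector lacks remains possible and was not examined here. No biological explanation was tested.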

How the results depend on the processing

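The tests on values as deposited, without the Z- and W-linked probe sets and with the delivered genes left out of the lists were chosen only after the data were seen, and the other alternatives before. Of 150 called values of genes followed through the settings, 30 passed in all 18 or in all in which they were tested, but 115 were lost without the intensity trend and 67 of 147 without control replicate 1. Of 34 list calls in 6 comparisons, all passed without the trend, without the pseudocount and with the pseudocount at the 50th percentile, 33 with only the 4 arrays compared, 33 with the replicate block, 33 with the delivered genes left out and 33 with the mean over probe sets, 32 with the filter at the 60th percentile and 32 without the Z- and W-linked probe sets, 31 with median centring, 30 as deposited, and 27 to 33 when 1 array was left out. The list test did not use the intensity trend, so leaving the trend out could neither lose nor gain a list call. Without the filter 29 passed and 5 were lost, of which the Notch list of Wnt2b against Delta-1 turned positive (0.064, adjusted p = 0.208). With the estimated correlation 0 lists passed in Wnt2b, 0 in Delta-1 and 0 in c-hairy1 against control, and 0 in Wnt2b against Delta-1. Signal over background limits dim genes, and under the 60th percentile filter the macrophage and microglia list was empty and had no test. Over the 156 tests of 26 lists in 6 comparisons, calls were also gained: 15 with the filter at the 60th percentile, 14 as deposited, 13 with median centring, 11 with the mean over probe sets, 5 with the pseudocount at the 50th percentile, 5 without the filter, 3 with the replicate block, 3 with the delivered genes left out, 2 with only the 4 arrays compared, 1 without the pseudocount, 0 without the trend, 0 without the Z- and W-linked probe sets, and 2 to 12 when 1 array was left out. Other than with the estimated correlation, the lists called ranged from 4 to 8 (4 in the main setting) in Wnt2b against c-hairy1 and from 3 to 10 (6) in c-hairy1 against Delta-1. Besides these and the values that follow, the other counts of probe sets and lists lay within 1.5 times the main count. Except where fewer arrays or other probe sets entered by construction, the cause was not tested.

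Without the intensity trend the calls were 28 (23 higher, 5 lower) for Wnt2b, 19 (4 and 15) for Delta-1 and 1 for c-hairy1 against control, 40 (28 and 12) for Wnt2b against Delta-1, 5 (3 and 2) for Wnt2b against c-hairy1 and 10 (9 and 1) for c-hairy1 against Delta-1, and 8 were higher with Wnt2b than with control and Delta-1. Without the filter they were, in that order, 238 (135 and 103), 227 (38 and 189), 1, 205 (115 and 90), 19 (10 and 9), 32 (28 and 4) and 51. With only the 4 arrays compared, Delta-1 had 590 (142 and 448) and c-hairy1 21 (17 and 4) against control, Wnt2b against c-hairy1 had 39 (26 and 13), and c-hairy1 against Delta-1 had 39 (30 and 9). Without a pseudocount Wnt2b against c-hairy1 had 22 (9 and 13). As deposited, Wnt2b against Delta-1 had 508 (141 and 367) and c-hairy1 against Delta-1 139 (43 and 96).

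Probe sets changed 2-fold in all array pairs numbered 546, 503 and 290 for Wnt2b, Delta-1 and c-hairy1 against control and 418 for Wnt2b against Delta-1 without the filter, where dim probe sets enter. With the larger pseudocount they numbered 130, 126, 20 and 109. Without a pseudocount c-hairy1 had 179 and Wnt2b against Delta-1 345. With the filter at the 60th percentile Wnt2b had 162, c-hairy1 25 and Wnt2b against Delta-1 121. The lists past the threshold for c-hairy1 against control went from 5 to 11 with that filter, 8 with median centring and 9 as deposited. Interferon, hypoxia and retinoic acid were added in all 3, Notch, photoreceptors and Mueller glia with that filter, and mesenchyme as deposited.

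With each array left out in turn, the remaining array of its group is assumed to vary like the other groups. The calls then ran from 62 to 583 for Wnt2b, from 53 to 440 for Delta-1 and from 1 to 6 for c-hairy1 against control, from 120 to 369 for Wnt2b against Delta-1, from 11 to 43 for Wnt2b against c-hairy1 and from 23 to 85 for c-hairy1 against Delta-1. Those higher with Wnt2b than with control and Delta-1 ran from 18 to 88. The correlations of effects ran from 0.418 to 0.676 for Wnt2b and Delta-1, from 0.456 to 0.70 for Wnt2b and c-hairy1 and from 0.404 to 0.708 for Delta-1 and c-hairy1. The lowest came without Delta-1 replicate 2 in the first pair and without c-hairy1 replicate 1 in the other 2, and the highest without control replicate 2. The correlation of unchanged groups that share controls also depends on the number of arrays per group. It was simulated only for all 8 arrays, so these ranges do not measure how far the shared effects vary. Lists past the threshold ran from 4 to 8 for c-hairy1 against control and from 4 to 11 for Wnt2b against Delta-1.

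Some list medians that did not pass changed sign. Against control, the ranges with 1 array left out were -0.105 to 0.045 for Wnt receptors and -0.148 to 0.245 for retinoic acid genes with Wnt2b, -0.083 to 0.014 for Wnt feedback and -0.143 to 0.121 for retinoic acid with Delta-1, and -0.011 to 0.131 for Wnt feedback and -0.046 to 0.07 for Wnt receptors with c-hairy1. In Wnt2b against c-hairy1 they were -0.222 to 0.01 for Notch and -0.108 to 0.103 for retinoic acid. With the mean over probe sets, the medians were 0.181 (Wnt receptors, Wnt2b), 0.037 (Wnt feedback, Delta-1), 0.175 (retinoic acid, Delta-1), 0.051 (Wnt feedback, c-hairy1) and -0.002 (Wnt receptors, c-hairy1) against control, and -0.032 for retinoic acid in Wnt2b against c-hairy1. With the filter at the 60th percentile they were 0.03 (Wnt feedback, Delta-1), 0.056 (retinoic acid, Delta-1) and 0.051 (Wnt feedback, c-hairy1) against control, and -0.328 for retinoic acid in Wnt2b against c-hairy1. Without the filter Wnt feedback in c-hairy1 against Delta-1 was -0.072.

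With median centring the medians were 0.083 (Wnt feedback, Delta-1), 0.092 (retinoic acid, Delta-1), -0.037 (Wnt receptors, c-hairy1) and -0.036 (retinoic acid, c-hairy1, adjusted p = 0.0482) against control. They were 0.05 for Wnt receptors and 0.017 for Notch in Wnt2b against c-hairy1, and -0.075 for Wnt feedback in c-hairy1 against Delta-1. As deposited, the same 7 were 0.077, 0.086, -0.101, -0.10 (adjusted p = 0.0284), 0.085, 0.052 and -0.133, and retinoic acid in Wnt2b against Delta-1 was -0.001. On that scale the median of all tested probe sets was 0.148 for Delta-1 and -0.118 for c-hairy1 against control. It was 0.094 in Wnt2b against c-hairy1, -0.257 in c-hairy1 against Delta-1 and -0.145 in Wnt2b against Delta-1. Each deposited list median had the sign of that shift and was smaller. Some of these lists also changed sign with the mean over probe sets or with another filter. Whether the scaling caused these sign changes was therefore not settled.

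With the replicate block, c-hairy1 against control had 13 calls (12 higher and 1 lower), and the other counts moved by less than 1.5 times. Across all tested probe sets the differences between replicates 1 and 2 correlated at -0.103 to 0.086 between groups. This shows no general pairing by replicate number but cannot exclude one. In the 12 W-linked probe sets called lower with Delta-1, replicate 2 lay above replicate 1 in control, Wnt2b and c-hairy1. For LOC430910 the signals were 378 and 736 in control, 335 and 715 with Wnt2b and 313 and 618 with c-hairy1. The exception was SPIN1L in control (80.2 and 73.2).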

Other observations

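The tests on sex-linked and neuronal genes in this part were chosen only after the result was seen, and the test on c-hairy1 with separate arrays was fixed before. Single genes of retinoid metabolism passed with Wnt2b and with Delta-1, although the list of 15 did not pass in any comparison against control. With Wnt2b, 4 of the genes rose, 1 fell and 10 did not pass over all genes, and the same numbers held when adjusted over the list alone. RDH10, which makes retinaldehyde from retinol, rose by 2.80 ± 0.25 (adjusted p = 0.000252), the retinol uptake receptor STRA6 by 1.31 ± 0.28 (0.0341), CYP1B1 by 1.23 ± 0.24 (0.0225) and the retinaldehyde dehydrogenase ALDH1A1 by 1.13 ± 0.16 (0.00436). The retinol carrier RBP4 fell by 1.14 ± 0.22 (0.0191). With Delta-1, ALDH1A1 (1.02 ± 0.16, adjusted p = 0.00603) and CYP26A1, which degrades retinoic acid (0.98 ± 0.18, 0.0164), rose, RBP4 fell by 1.25 ± 0.22 (0.0114), and 12 did not pass, among them RDH10 (0.60, 0.346). ALDH1A1 and RBP4 are on chromosome Z, and the Z- and W-linked medians with Delta-1 were 0.24 and -1.74. The list's median with Delta-1 was -0.09 (mean -0.03, camera Up, adjusted p = 0.997), or 0.09 with median centring and on the deposited scale. STRA6 with Wnt2b was chosen after its value was seen.

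Between Wnt2b and Delta-1 the difference itself was tested. RDH10 (2.19 ± 0.25, adjusted p = 0.000866), STRA6 (1.96 ± 0.28, 0.00381) and CYP1B1 (1.32 ± 0.24, 0.016) were higher with Wnt2b, CYP26A1 was lower (-1.38 ± 0.18, 0.00231) and 11 did not pass (3 higher and 2 lower over the list alone), beside a W-linked median of 1.67. The list had a median of 0.18 (camera adjusted p = 0.253). Between Wnt2b and c-hairy1 0 of the 15 passed in limma in their brightest probe sets, with 5 at an unadjusted p under 0.05 (list median 0.08, camera adjusted p = 0.981). Another probe set of RDH10 passed there in limma (1.34, adjusted p = 0.0438), while its brightest (1.33, 0.054) and a further one (1.22, 0.0762) did not. With c-hairy1 0 of the 15 passed in limma over all genes, 5 had an unadjusted p under 0.05 and 5 were higher when adjusted over the list alone (median 0.02, camera adjusted p = 0.103, and adjusted p = 0.35 with an estimated correlation). The smallest p belonged to CYP1B1 (1.38, adjusted p = 0.126), RDH10 (1.47, 0.126), ALDH1A1 (0.80, 0.169) and ALDH1A3 (1.12, 0.373). That list, with camera direction Up in the main setting, passed with the filter at the 60th percentile (0.14, camera adjusted p = 0.00469) and with the mean over probe sets (0.18, 0.0152). Without control replicate 1 its median was 0.25. It also passed with median centring (-0.04, adjusted p = 0.0482) and on the deposited scale (-0.10, 0.0284). On the deposited scale the median of all tested probe sets was -0.118, so -0.10 was no decrease relative to them.

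Of 24 W-linked probe sets 12 fell with Delta-1, to signals of 0.446 to 90.4, while 8, of MBD2, NEDD4L, LOC425347 and UBAP2L2, had log2 fold changes of -0.32 to 0.20. The rest were lower but did not pass: LOC426615 (-1.49), LOC431003 (-0.93) and other probe sets of HNRNPKL (-1.39) and UBAP2L2 (-1.32). Scaling between arrays is argued against, since the highest median of all 24 under the 3 scalings was -1.737. Few or no female embryos among the Delta-1 retinas may account for the decreases, as female birds carry the W and males a second Z. The Z-linked minus other median was above 0 in all 12 pairs of a Delta-1 array with another array, with a median of 0.192, but the smallest, 0.098, did not exceed the largest of the 15 pairs of other arrays, 0.114. A response of the W-linked genes alone to Delta-1 cannot be told apart from it by these values, because only 2 arrays carry the shift and the sex of the embryos is not given in the sources used here.

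Neuronal and proneural genes were lower in the same Delta-1 arrays. A dose effect on members that are themselves Z- or W-linked is argued against for 25 of the 27 called members, which lie on other chromosomes. With 776 Z-linked and 24 W-linked tested probe sets against 16877 on other chromosomes, such a count was likely beforehand. Scaling is argued against too, since the highest of the 3 medians of all 49 tested members was -1.178. The sex of the embryos acting on genes of other chromosomes cannot be told apart from Delta-1 here, because 0 Delta-1 arrays had a W-linked median above -1 against control. The biological explanation that the design gives, Delta-1 itself, likewise stays open.

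A hypothesis on sharing between treatments was tested on separate arrays, without the delivered genes and chromosomes Z and W. Of 145 probe sets higher with Wnt2b than with Delta-1, 89 were higher and 56 lower in c-hairy1 than in control, with a median of 0.132, at percentile 100 of 10000 random lists matched on mean signal (95% of them between -0.044 and 0.043). Whether these genes respond to Wnt2b or to Delta-1 was not part of this test, and the random lists treat probe sets as independent. The 135 probe sets lower with Wnt2b than with Delta-1 gave a negative result, a median of 0.008 with 68 higher and 67 lower, against 95% of random lists between -0.038 and 0.04 (percentile 60.13).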
